A study of Homo sapiens with 6 samples.

How the data were processed

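The series holds RNA-seq libraries of total RNA from T24 cells, 3 labelled as Control and 3 as treated with DON, each for 48 h. Per the labels' protocols, cells grew in DMEM with serum, RNA was extracted with TRIzol, and libraries made with a VAHTS Universal kit were sequenced on an Illumina NovaSeq. Whether the kit kept strand, whether reads were paired and whether replicates were separate cultures is not given in the sources used here.

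The authors deposited raw read counts per gene, which are whole numbers that sum to different totals in each library, per the file headers and the values. The submitters' processing notes name HISAT2 2.0.5 and featureCounts 1.5.0-p3. The genome build and the annotation are not given in the sources used here, so no coordinates are printed. The authors also deposited FPKM values for the same 6 libraries, per the file headers. Within a library, the deposited FPKM values are proportional to the count divided by a gene-specific length. Their implied library denominators differed from the column sums of the counts by a factor of 0.9853 to 1.0058, relative to Control replicate 1. The deposited table further holds the authors' own log2 fold change of DON against Control and a p-value for 15892 genes. The tool behind them, and whether the p-value is adjusted, is not given in the sources used here. The comparison column entered no test.

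The table has 65807 rows, of which 19123 have a count in at least 1 library. Gene identifiers are NCBI Gene IDs paired with symbols in the table, and 99.91% of those with a count were found in the NCBI gene table for GRCh38.p14, which was used for names only. Among genes with a count, 4 rows that repeated another row's symbol and counts (MEMO1, TEC, HBD and MMD2) were removed, which left 15890 genes with a fold change by the authors. No row lacked a gene, and 0 per-sample columns were left unused. A gene listed at 0 in all libraries is not called silent, because genes whose symbol changed between annotation releases were nearly always listed at 0.

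Depth was 29616156 to 36526344 counts per library. At this depth a count of 0 allows up to 3 counts, or 0.0821 to 0.1013 CPM, in a library. Intervals and floors cover counting error only. Between 15740 and 16047 genes had a count in a Control library and between 16224 and 16517 in a DON library. The 10 most abundant genes took 6.21% to 6.66% of the counts in Control and 4.38% to 4.63% in DON. Pairs of libraries within a group differed by more than sampling noise (chi-square over degrees of freedom 4.89 to 24.04 over genes with at least 10 counts), so none was treated as a library deposited more than once.

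Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr, libraries were scaled by TMM, and DON was compared with Control by glmQLFit and glmQLFTest with no covariate, two-sided, with Benjamini-Hochberg adjustment at 0.05. The design had foreseen limma on FPKM in case no counts were found, and the branch for counts applied. The common biological coefficient of variation was 0.091. The standard error of a fold change is its size divided by the square root of the quasi-likelihood F. CPM values are scaled by TMM. For named genes with 1 to 3 counts in a group, the ratio of counts is given with an exact (Clopper-Pearson) 95% interval.

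Before the data were examined, 35 gene lists were fixed for a glutamine antagonist in a bladder cancer line, among them luminal and basal urothelial markers and markers of leukocytes, fibroblasts and endothelial cells. The 33 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Counts of members that rose or fell use the adjustment over all genes and, where named so, the adjustment over the list alone. The rule for named genes, also fixed before, took the 8 largest rises and the 8 largest falls among genes with an adjusted p under 0.05, no overlap between the groups and a mean of at least 1 CPM. It added a panel of 12 genes and up to 4 members of each list with the smallest p. Not every gene that this rule selects is named in the text. KCNJ2, EEF1A1, the EGFR ligands EGF, TGFA, EREG, BTC and EPGN, and the gene families of the closing section were chosen after their values were seen. The gene name resources were also used to compare each protein-coding gene's symbol with its GENCODE 29 symbol through the NCBI Gene ID.

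The alternatives fixed before were the replicate number as a block, leaving out each of the 6 libraries, DESeq2 size factors in edgeR, no scaling beyond library size, at least 1 count in any library in place of filterByExpr, the DESeq2 1.42.0 Wald test, limma with a trend on log2(FPKM + 1), camera with an estimated correlation, and fry. Fold changes on the log2(FPKM + 1) scale understate the change of genes with low values. Alternatives foreseen for a table with FPKM alone were not run, since counts were present.

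The tests were run first on simulated counts for the comparison of DON with Control, with 200 of 13361 genes changed. The edgeR test recovered 68.7% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 97.0% of those changed 4-fold with the right sign, and 7.6% of its calls were unchanged genes. For DESeq2 these values were 67.2%, 89.6%, 97.0% and 12.4%. In the same simulation, camera gave a list of 30 unchanged genes an adjusted p of 0.586 and a list of 30 raised genes one of 4.7e-188. Genes were drawn there independently of each other, and far fewer were changed than in the data. With a single unchanged list, this does not show how often camera calls lists of correlated genes falsely.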

Results

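Gene expression was measured by RNA sequencing in T24, an established human bladder cancer cell line, after 48 h with DON or after 48 h under normal culture conditions (Control). DON is taken here to be 6-diazo-5-oxo-L-norleucine, a glutamine analogue that blocks enzymes using glutamine as a nitrogen donor. The labels give only the abbreviation, and the series title speaks of glutamine blockade. There were 6 libraries, 3 per group. Total counts per library were 32896488, 34085794 and 29616156 in Control replicates 1, 2 and 3 and 30389029, 30179357 and 36526344 in DON replicates 1, 2 and 3. The comparison asks which transcripts differ when glutamine use is blocked. The series title also names gefitinib, an inhibitor of the EGFR kinase, and a suppressed immune response, so EGFR signalling and immune genes were among the gene lists fixed before the data were examined. No library with gefitinib was among those analysed here. Levels are given as CPM (counts relative to library size, after TMM scaling), as mean ± SD over n = 3 libraries. Fold changes are log2 values of DON against Control with the standard error (SE), and adjusted p-values are Benjamini-Hochberg values of the edgeR quasi-likelihood test unless another test is named.

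DON changed the levels of most genes that could be tested in T24 cells. Of 13361 genes, 3920 rose and 3546 fell, together 7466 or 55.9%. By at least 2-fold, 936 genes rose and 512 fell, 1448 in all. The groups did not overlap for 8246 genes (61.7%), where chance gives 10%. The split between rises and falls depended on scaling: 52.5% of changed genes were higher with TMM scaling, 50.6% with DESeq2 size factors and 64.4% with no scaling beyond library size. Among genes changed at least 2-fold the corresponding shares were 64.6%, 62.8% and 76.0%. With limma on log2(FPKM + 1) values, where test, scale and scaling all differ, the shares were 67.5% and 85.0%. Without scaling the median log2 fold change of all genes was 0.126, against 0.014 with TMM.

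Among the largest rises of genes with a mean of at least 1 CPM, IL24, a cytokine of the interleukin-10 family, went from 1.10 ± 0.496 to 107.2 ± 4.43 CPM, a log2 fold change of 6.62 (SE 0.167, adjusted p = 1.77e-15). ANKRD1, a transcriptional cofactor, went from 0.556 ± 0.168 to 71.2 ± 15.3 CPM (log2 fold change 6.98). IL1RL1, the receptor for interleukin-33, rose with a log2 fold change of 6.43 (SE 0.193), and the matrix metalloproteinase MMP3 rose from 0.668 ± 0.283 to 50.9 ± 10.5 CPM. RBBP8NL had 1 count in the Control libraries together and 2309 in the DON libraries. The ratio of its scaled counts was 2130 with a 95% counting interval of 381 to 84000, and its fitted log2 fold change of 10.63 depends on the prior count. STMN4, a stathmin family member, had 2 counts against 221, a ratio of 102 with an interval of 27.8 to 846. C2orf78 rose with a log2 fold change of 6.17 to 4.96 ± 1.22 CPM. RPLP0P2 rose with a log2 fold change of 5.60. It is a pseudogene of the ribosomal protein gene RPLP0, so the origin of its reads is uncertain. The NCBI Gene identifiers of these genes are 11009 for IL24, 27063 for ANKRD1, 9173 for IL1RL1, 4314 for MMP3, 140893 for RBBP8NL, 81551 for STMN4, 388960 for C2orf78 and 113157 for RPLP0P2.

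Among genes with a mean of at least 1 CPM and no overlap between the groups, the largest fall was that of CDH6, a cadherin, from 2.01 ± 0.775 to 0.0902 ± 0.0346 CPM (log2 fold change -4.43, SE 0.507, adjusted p = 7.15e-07). CP, which encodes the copper carrier ceruloplasmin, fell from 9.77 ± 1.82 to 0.835 ± 0.0947 CPM. IDO1, an enzyme that breaks down tryptophan, fell from 1.83 ± 0.234 to 0.263 ± 0.191 CPM (log2 fold change -2.73). The membrane protein gene SLITRK6 had a log2 fold change of -2.68, the protease inhibitor gene SERPINA5 one of -2.52 and PIR, an iron-binding nuclear protein gene, one of -2.49. KCNJ2-AS1 had a log2 fold change of -2.72. It is antisense to KCNJ2, whose own log2 fold change was -1.78, and since no source used here says that counting used strand, reads of the pair cannot be told apart. ESPNP, with a log2 fold change of -2.36, is a pseudogene copy of ESPN and its reads are likewise uncertain. The NCBI Gene identifiers are 1004 for CDH6, 1356 for CP, 3620 for IDO1, 84189 for SLITRK6, 5104 for SERPINA5, 8544 for PIR, 400617 for KCNJ2-AS1 and 284729 for ESPNP.

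Genes of glutamine use went in both directions. GLUL, which makes glutamine from glutamate, was at 107.5 ± 3.62 and 110.1 ± 3.23 CPM (adjusted p = 0.711). The glutamine carrier gene SLC1A5 was at 200.6 ± 27.9 and 185.7 ± 8.16 CPM (adjusted p = 0.285). Of 11 measured enzymes that use glutamine, 4 rose, 3 fell and 4 did not pass the test, with the same counts adjusted over the list alone, and 6 rose and 3 fell without scaling. CAD of pyrimidine synthesis (log2 fold change 0.50) and GFPT1 (0.71) rose, while CTPS2 (-1.05), NADSYN1 (-0.61) and GMPS (-0.41) fell. By camera, a test of whether a list's genes rank above or below the other genes, this list gave an adjusted p of 0.89. Fry, which tests whether a list's genes move on balance in a direction, gave it an adjusted p of 0.0153 (up). Among 15 other enzymes of glutamine and glutamate metabolism, 3 rose and 9 fell, the same when adjusted over the list alone. Without scaling 3 rose and 7 fell (camera adjusted p = 0.142, fry adjusted p = 0.00131, down). Those that fell included PSAT1 (-0.79), PYCR1 (-0.74), ALDH18A1 (-0.51) and GPT2 (-0.41), enzymes of serine, proline and alanine synthesis. Of 25 amino acid transporters 9 rose and 7 fell, the same adjusted over the list alone, and 10 rose and 5 fell without scaling (camera adjusted p = 0.862). SLC3A2, the shared heavy chain of several transporters, rose from 447.6 ± 59.2 to 1044 ± 53.3 CPM and the lysosomal carrier SLC36A1 rose from 18.2 ± 2.38 to 54.3 ± 3.01 CPM. The cystine carrier SLC7A11 fell from 75.0 ± 17.7 to 21.3 ± 0.646 CPM and the taurine carrier SLC6A6 had a log2 fold change of -1.11.

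Targets of ATF4, the transcription factor of the amino acid response, went in both directions: of 32 measured, 10 rose, 12 fell and 10 did not pass, or 11 and 13 adjusted over the list alone, and 11 rose and 10 fell without scaling (camera adjusted p = 0.895). DDIT3, a stress-induced transcription factor gene (NCBI Gene 1649), rose from 15.2 ± 2.32 to 71.3 ± 2.21 CPM (log2 fold change 2.23, SE 0.107, adjusted p = 1.04e-11), and ATF3 rose from 9.26 ± 0.158 to 40.1 ± 1.95 CPM. DDIT4, an inhibitor of mTORC1 signalling, fell from 463.6 ± 62.8 to 150.6 ± 18.5 CPM. PHGDH, the first enzyme of serine synthesis, fell from 552.6 ± 35.3 to 247.9 ± 12.1 CPM. ASNS, the glutamine-dependent asparagine synthetase (NCBI Gene 440), was at 4.13 ± 0.793 CPM in Control and 4.66 ± 0.629 CPM in DON (log2 fold change 0.17, adjusted p = 0.468). Of 20 aminoacyl-tRNA synthetase genes on the list, 18 were listed at 0 in every library, as were all 13 mitochondrially encoded mRNAs, and neither list was tested. The 2 measured synthetase genes, FARSA (0.84) and FARSB (0.55), rose.

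Chaperones and degradation factors of the endoplasmic reticulum fell as a group. Of 22 unfolded protein response genes 15 fell and 2 rose, or 16 and 2 adjusted over the list alone (camera adjusted p = 7.15e-08; adjusted p = 0.227 with an estimated correlation). The chaperone HSP90B1 fell from 1062 ± 87.1 to 438.9 ± 20.1 CPM, PDIA4 from 562.5 ± 21.5 to 232.4 ± 3.91 CPM, PDIA6 from 355.9 ± 11.5 to 171.4 ± 8.14 CPM and CRELD2 from 73.7 ± 5.44 to 26.7 ± 1.66 CPM. The list of the hexosamine pathway, which makes the sugar donor UDP-GlcNAc, and of UDP-GlcNAc use rose as a group. Of its 15 tested genes 10 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.00513, or 0.227 with an estimated correlation). It also holds enzymes that run the pathway in reverse or use its product. Of the synthesis itself, GFPT1, GNPNAT1 (0.57) and UAP1 (0.47) rose. PGM3 (-0.05) and GFPT2 (0.12) were among the 4 genes of the list that did not pass. GFPT1, the pathway's glutamine-dependent first enzyme (NCBI Gene 2673), rose from 60.8 ± 4.03 to 99.5 ± 2.42 CPM (SE 0.078, adjusted p = 4e-07). GNPDA1, which runs the same step in reverse, rose from 102.6 ± 1.30 to 261.4 ± 11.2 CPM, UAP1L1 rose with a log2 fold change of 0.90 and RENBP with one of 2.06. The gene that fell was OGT, the transferase that uses UDP-GlcNAc to modify proteins, from 432.6 ± 44.8 to 263.2 ± 9.87 CPM.

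Genes of mitosis fell and genes of ribosome assembly rose. Of 34 mitosis genes 31 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 1.52e-11; adjusted p = 0.316 with an estimated correlation). The kinesin gene KIF20A fell from 137.6 ± 13.2 to 47.3 ± 1.13 CPM, cyclin gene CCNB1 from 286.6 ± 14.9 to 140.4 ± 2.27 CPM, and the kinase gene PLK1 and the kinetochore gene CENPF had log2 fold changes of -1.02 and -1.06. Genes of DNA replication were mixed, with 8 of 33 higher and 9 lower, the same adjusted over the list alone, and 12 higher and 8 lower without scaling (camera adjusted p = 0.862). E2F1 (0.71) and RFC3 (0.62) rose and MCM6 (-0.83) and LIG1 (-0.64) fell. The cyclin-dependent kinase inhibitor CDKN1A (NCBI Gene 1026) rose from 76.0 ± 2.93 to 228.2 ± 13.2 CPM (log2 fold change 1.59, SE 0.073, adjusted p = 7.04e-12). Across 22 p53 target genes, however, 6 rose and 9 fell, the same adjusted over the list alone, and 7 rose and 5 fell without scaling (camera adjusted p = 0.737). GADD45A (1.91) and AEN (1.23) were among those that rose and FDXR (-1.16) among those that fell.

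Ribosome biogenesis genes rose in 22 of 26 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 7.53e-07; adjusted p = 0.366 with an estimated correlation). RRP12 rose from 147.5 ± 18.8 to 536.3 ± 22.2 CPM, RRS1 from 36.1 ± 5.70 to 99.9 ± 3.70 CPM and GNL3 from 74.6 ± 8.72 to 151.2 ± 10.6 CPM. MYC, a transcription factor gene on the same list (NCBI Gene 4609), rose from 63.6 ± 1.02 to 121.3 ± 5.42 CPM (log2 fold change 0.93, SE 0.073, adjusted p = 6.33e-09). Listed genes for proteins of the cytosolic ribosome itself moved the other way. The list does not hold all such genes, and RPL27A (-1.095), for example, is not on it. Of the 45 listed genes 36 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 5.41e-10, or 0.366 with an estimated correlation). Without scaling, 30 of them fell and 4 rose. RPL4 fell from 1900 ± 32.5 to 997.7 ± 13.9 CPM, RPSA from 2157 ± 70.7 to 1186 ± 27.2 CPM, RPL15 from 1680 ± 70.0 to 931.8 ± 29.6 CPM and RPL22 from 414.8 ± 26.6 to 213.2 ± 1.36 CPM. These genes have many pseudogene copies, and the counting could split reads among them. Nucleotide synthesis showed no common direction. Of 11 purine synthesis genes 4 rose and 4 fell, or 5 and 3 without scaling (camera adjusted p = 0.862), and of 15 pyrimidine and dNTP genes 4 rose and 4 fell (camera adjusted p = 0.803), both 4 and 4 adjusted over the list alone. PRPS1 (0.41), ATIC (0.35) and UMPS (0.54) rose, while IMPDH2 (-0.73), GMPS and TYMS (-0.42) fell.

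**Figure D1:**
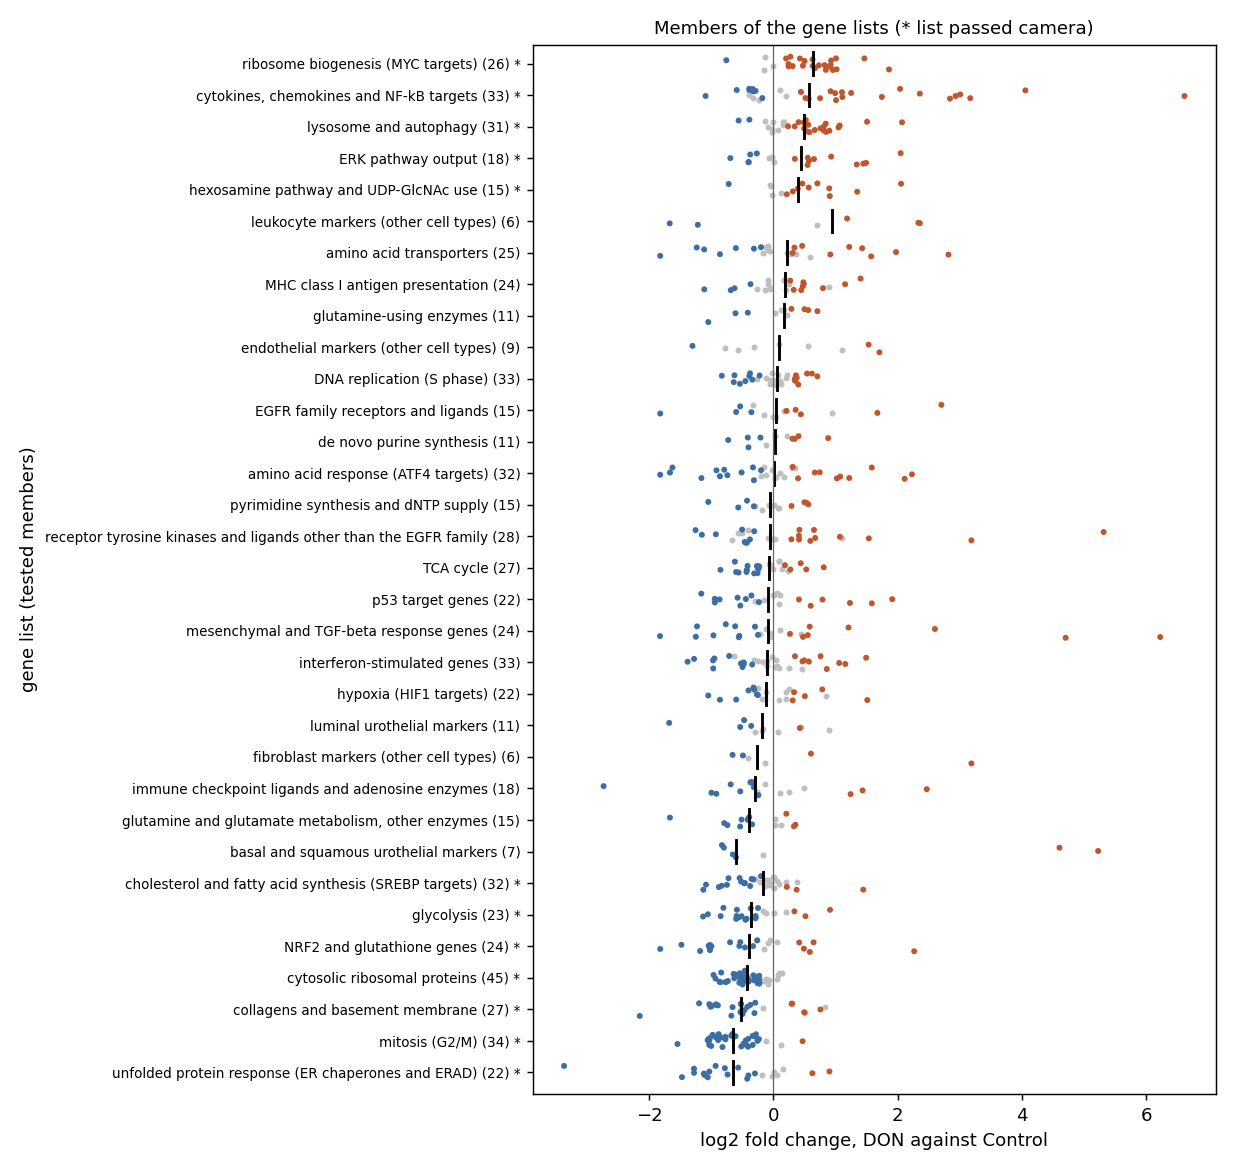
Log2 fold change of each tested member (points, horizontal axis) of the 33 tested gene lists (rows, number of tested members in brackets). Orange and blue points are members that rose or fell at an adjusted p under 0.05, grey points did not pass, black bars are medians, and an asterisk marks the 12 lists past the camera threshold, from ribosome biogenesis (22 of 26 rose) at the top to the unfolded protein response (15 of 22 fell) at the bottom.

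Glycolysis genes fell as a group. Of 23 glycolysis genes 16 fell and 3 rose, or 16 and 4 adjusted over the list alone (camera adjusted p = 0.000776; adjusted p = 0.538 with an estimated correlation). LDHA fell from 2088 ± 60.9 to 1160 ± 60.9 CPM, PKM from 4840 ± 408 to 2775 ± 114.7 CPM, PFKL from 255.7 ± 23.8 to 123.4 ± 14.2 CPM and the lactate carrier SLC16A3 from 866.9 ± 84.6 to 396.1 ± 42.5 CPM. Genes of NRF2 output and glutathione fell in 14 of 24 cases and rose in 5, the same adjusted over the list alone (camera adjusted p = 0.000776; adjusted p = 0.227 with an estimated correlation). TKT (-1.18) and TALDO1 (-1.04), enzymes of the pentose phosphate pathway, fell, and OSGIN1, a growth inhibitor gene, rose with a log2 fold change of 2.27. Of 32 genes of cholesterol and fatty acid synthesis 14 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.0175; adjusted p = 0.227 with an estimated correlation). The fatty acid genes SCD (-1.08), FADS2 (-1.13) and FASN (-0.83) fell, and LSS, which makes lanosterol in sterol synthesis, rose from 116.9 ± 13.4 to 318.9 ± 24.2 CPM. Among 27 genes of the TCA cycle 13 fell and 5 rose, the same adjusted over the list alone, and 7 fell and 7 rose without scaling (camera adjusted p = 0.447), with ACO1 (-0.56) and PCK2 (-0.62) lower and IDH3A (0.81) and SDHB (0.53) higher. Hypoxia targets were split, with 5 of 22 higher and 8 lower, or 6 and 8 adjusted over the list alone, and 8 higher and 5 lower without scaling (camera adjusted p = 0.862). ANGPTL4 (1.51) and ADM (0.79) rose, and KDM4B (-0.86) and EGLN3 (-1.05) fell.

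Genes of lysosomes and autophagy rose: 20 of 31 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 8.55e-06; adjusted p = 0.227 with an estimated correlation). The lysosomal calcium channel gene MCOLN1 rose from 14.8 ± 0.916 to 62.2 ± 5.63 CPM and the sialidase gene NEU1 from 45.8 ± 2.02 to 130.2 ± 11.4 CPM. FLCN, a regulator of lysosomal nutrient sensing, had a log2 fold change of 1.07, and MAP1LC3B, which encodes a protein of autophagosome membranes, one of 1.05.

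EGFR mRNA itself (NCBI Gene 1956) was at 455.8 ± 13.2 CPM in Control and 470.3 ± 15.2 CPM in DON, a log2 fold change of 0.05 (SE 0.065, adjusted p = 0.577). Its value passed the threshold with no scaling beyond library size (log2 fold change 0.16, adjusted p = 0.0385) and on log2(FPKM + 1) values (0.17, adjusted p = 0.0252). Over the alternative settings its adjusted p ranged from 0.0252 to 0.847. Of the ligands of EGFR, AREG (NCBI Gene 374) rose from 2.62 ± 0.911 to 17.2 ± 0.677 CPM (log2 fold change 2.70, SE 0.189, adjusted p = 1.44e-09) and HBEGF rose from 26.9 ± 1.01 to 86.0 ± 4.48 CPM. TGFA rose as well (0.44), and EGF fell from 1.42 ± 0.168 to 0.406 ± 0.127 CPM (log2 fold change -1.82, adjusted p = 0.000733, in a range over settings of 9.15e-05 to 0.0123). EREG (adjusted p = 0.392, range 0.00949 to 0.947), BTC (0.702, range 0.193 to 0.941) and EPGN (0.135, range 0.0475 to 0.385) did not pass. ERBB2 (-0.53) and the ligand-shedding protease gene ADAM10 (-0.60) fell. The list of this family holds 15 measured genes, which are receptors, ligands and the proteases ADAM10 and ADAM17. Of these 5 rose and 4 fell, the same adjusted over the list alone, and 6 rose and 3 fell without scaling (camera adjusted p = 0.587). Genes of the ERK pathway output list, induced by this signalling, rose in 10 of 18 cases and fell in 5, the same adjusted over the list alone (camera adjusted p = 0.0438; adjusted p = 0.575 with an estimated correlation). The phosphatases DUSP5 (1.45) and DUSP4 (1.34), which act as feedback inhibitors of MAP kinases, and the transcription factor gene EGR1 (2.05) rose. CCND1 (-0.69), FOSL1 (-0.40), ETV4 (-0.40), ETV5 (-0.37) and PHLDA1 (-0.26) of the same list fell. This list lost its call without Control replicate 1 (adjusted p = 0.101), Control replicate 2 (0.0783) or DON replicate 2 (0.0569) and on log2(FPKM + 1) values (0.212), in a range over settings of 0.0038 to 0.212. Of 28 other receptor tyrosine kinases and ligands 11 rose and 9 fell, or 11 and 10 adjusted over the list alone, and 11 and 8 without scaling (camera adjusted p = 0.86). FGF1 rose from 0.219 ± 0.0672 to 8.73 ± 1.94 CPM and FGF2 from 28.1 ± 4.87 to 59.2 ± 1.93 CPM, and GAS6 (-0.92) and PDGFA (-1.15) fell.

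Among immune genes, the checkpoint ligand gene CD274, which encodes PD-L1 (NCBI Gene 29126), rose from 10.0 ± 1.75 to 55.2 ± 4.80 CPM, a log2 fold change of 2.47 (SE 0.123, adjusted p = 1.6e-11). PDCD1LG2, which encodes the other ligand of the same receptor, rose from 4.40 ± 0.436 to 11.9 ± 1.23 CPM, and PVR, a ligand of TIGIT, rose from 102.3 ± 6.88 to 242.3 ± 9.17 CPM. These were the 3 of 18 measured checkpoint and adenosine genes that rose. A further 10 fell, among them IDO1 and the adenosine-forming enzyme gene NT5E, which fell from 159.6 ± 9.25 to 84.6 ± 0.730 CPM. The counts were the same adjusted over the list alone, 3 rose and 6 fell without scaling, and the list did not pass (camera adjusted p = 0.791). B2M, the light chain of MHC class I (NCBI Gene 567), was at 536.2 ± 61.9 and 601.5 ± 22.6 CPM, higher in 3 of 3 DON libraries with an adjusted p of 0.0842. It passed without Control replicate 2 (log2 fold change 0.20, adjusted p = 0.0286), without scaling (0.28, adjusted p = 0.00737) and on log2(FPKM + 1) values (0.30, adjusted p = 0.0196), and over all settings its adjusted p ranged from 0.00737 to 0.336. Of 24 genes of MHC class I presentation 9 rose and 4 fell, the same adjusted over the list alone, and 12 rose and 4 fell without scaling (camera adjusted p = 0.737). HLA-B rose with a log2 fold change of 1.41, though reads of near-identical class I genes may be split or lost, and ULBP2 (1.16), a ligand of the NKG2D receptor, rose. TAPBP (-1.11) and PSME1 (-0.68), which act in peptide loading and the proteasome, fell. Interferon-stimulated genes were split, 9 of 33 higher and 11 lower, or 9 and 12 adjusted over the list alone, and 9 and 10 without scaling (camera adjusted p = 0.737). ISG15 (1.06) and ISG20 (1.49) rose and BST2 (-0.95) and IFIT1 (-1.27) fell.

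Cytokine, chemokine and NF-kB target genes rose as a group: 19 of 33 rose, 13 of them by at least 2-fold, and 8 fell, or 20 and 8 adjusted over the list alone (camera adjusted p = 3.12e-16; adjusted p = 0.241 with an estimated correlation). IL11, a cytokine of the interleukin-6 family, rose from 14.9 ± 0.804 to 248.3 ± 6.66 CPM, a log2 fold change of 4.06 (SE 0.082, adjusted p = 9.9e-17). The neutrophil-attracting chemokine genes CXCL8 and CXCL3 rose from 191.7 ± 25.9 to 1465 ± 71.6 CPM and from 18.7 ± 1.10 to 150.5 ± 7.49 CPM. TNFAIP2 (-1.09), TNF (-0.38) and NFKBIA (-0.32) were among the 8 that fell.

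**Figure D2:**
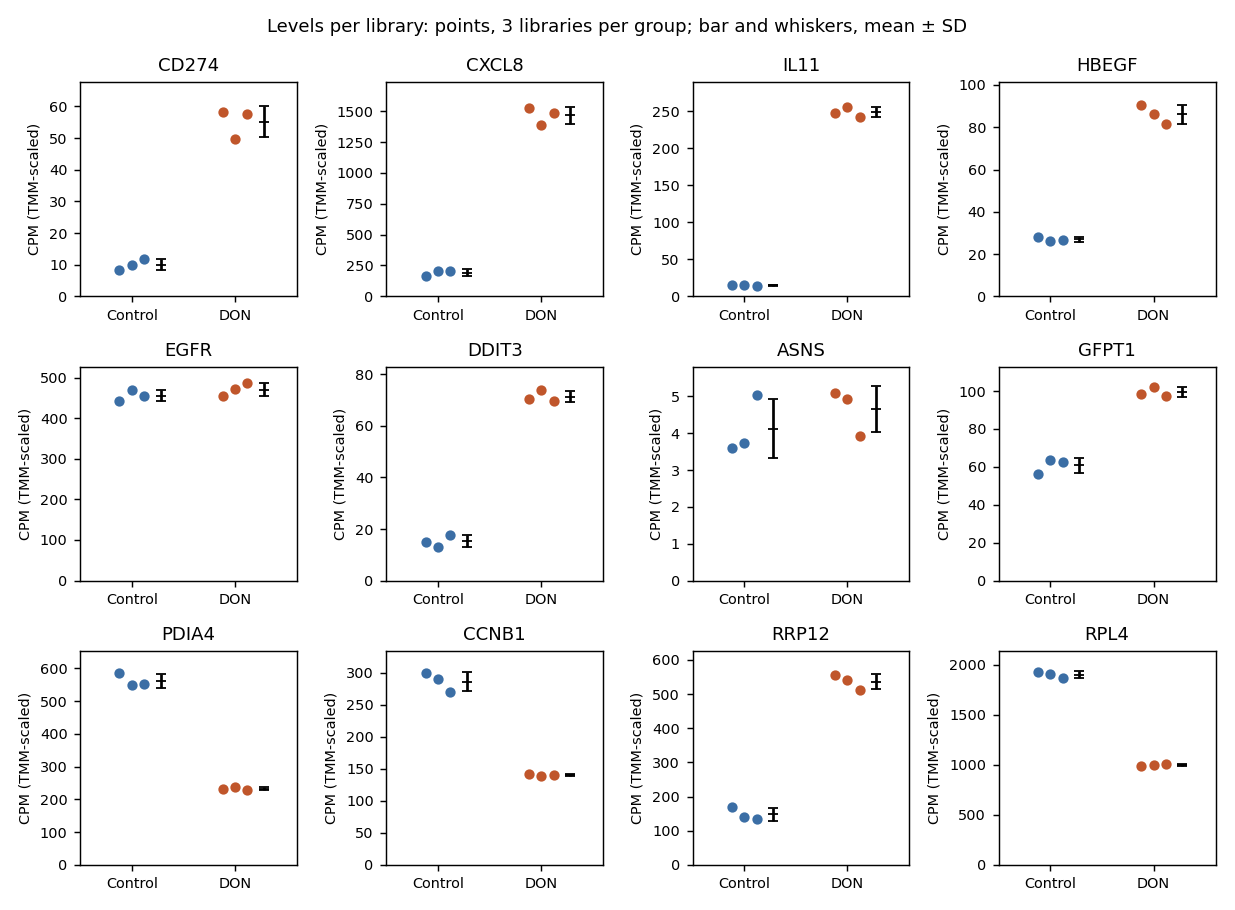
TMM-scaled CPM (vertical axes, each from 0) of 12 genes in each of the 3 Control (blue) and 3 DON (orange) libraries, with the mean and SD of each group in black. CD274, CXCL8, IL11, HBEGF, DDIT3, GFPT1 and RRP12 lie higher in every DON library, PDIA4, CCNB1 and RPL4 lower, and the values of EGFR and ASNS overlap.

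Genes of basement membrane and collagens fell in 19 of 27 cases and rose in 5, or 20 and 5 adjusted over the list alone (camera adjusted p = 2.7e-06; adjusted p = 0.411 with an estimated correlation). COL18A1 fell from 452.3 ± 45.6 to 102.1 ± 6.29 CPM, the laminin gene LAMA5 from 1597 ± 155.8 to 697.7 ± 64.7 CPM, COL4A1 from 187.0 ± 9.58 to 94.3 ± 4.05 CPM and LAMB1 from 429.0 ± 28.5 to 226.1 ± 8.02 CPM. Mesenchymal and TGF-beta response genes were mixed, with 8 of 24 higher and 10 lower, or 9 and 11 adjusted over the list alone, and 9 higher and 8 lower without scaling (camera adjusted p = 0.803). The collagenase gene MMP1 rose from 2.18 ± 0.758 to 56.8 ± 4.60 CPM along with MMP3, while the matrix genes TGFBI (-1.82) and SPARC (-1.23) fell. Of 11 measured luminal urothelial markers 1 rose and 4 fell, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.418), with ELF3 (-1.68), KRT8 (-0.47) and KRT7 (-0.36) lower. Of 7 basal and squamous markers 2 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.334). KRT17 rose from 0.282 ± 0.102 to 10.6 ± 1.32 CPM and the elastase inhibitor gene PI3 from 2.07 ± 0.541 to 50.1 ± 4.13 CPM, while CD44 (-0.65) and ITGA6 (-0.60) fell.

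Markers of other cell types, measured here only as expression in a cell line, did not move together. Of 6 measured leukocyte markers 3 rose and 2 fell, the same adjusted over the list alone, and 3 rose and 1 fell without scaling (camera adjusted p = 0.649). ITGAX rose to 5.75 ± 0.971 CPM, CD8A to 5.87 ± 0.300 CPM and ITGAM to 1.24 ± 0.388 CPM, and CD14 fell to 1.33 ± 0.394 CPM. Of 6 fibroblast markers 2 rose and 2 fell, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.803). C1S (0.61) and PDGFRA (3.19, to 0.621 ± 0.194 CPM) rose, and FBLN1 (-0.49) and COL1A1 (-0.66) fell. The rise of PDGFRA did not pass on log2(FPKM + 1) values (0.042, adjusted p = 0.0532, in a range over settings of 0.000201 to 0.0532). Of 9 endothelial markers 2 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.668). TIE1 (1.71) and ESAM (1.53) rose and CDH5 (-1.30) fell. EGFL7 had a log2 fold change of -0.31 (adjusted p = 0.055) and passed with the replicate block (-0.30, adjusted p = 0.039), DESeq2 size factors (0.0375), the DESeq2 Wald test (0.0398) or no low-count filter (0.0174). It also passed without Control replicate 1 (-0.37, adjusted p = 0.032), Control replicate 2 (-0.44, adjusted p = 0.00404) or DON replicate 2 (-0.41, adjusted p = 0.0351), in a range of 0.00404 to 0.38.

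The first principal component, which separated the groups, held 75.5% of the variance and the second 8.6%. Log CPM values correlated across genes at r = 0.9882 to 0.9932 within groups and 0.9551 to 0.9595 between them, where genes are not independent replicates. In the authors' deposited table, 15890 genes had a fold change and 1680 of them a p under 0.05 with at least a 2-fold change, 1083 higher and 597 lower. Across the 13361 shared genes its log2 fold changes had r = 0.9996 with those given here, 99.09% had the same sign, and the largest difference among genes with a mean of at least 1 CPM was 0.32.

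Nothing in the labels says whether the 3 replicates were separate cultures, so p-values measure only the spread between these samples. None of the 12 list calls held with an estimated correlation, where the 6 libraries leave few degrees of freedom. Camera with a preset correlation called up to 10 lists when Control and DON libraries were mixed. Each mixed split keeps part of the difference between DON and Control, so these calls do not give a rate of false calls. Test, median and mean differed in sign for several lists that did not pass: the median and mean were 0.01 and 0.03 for the ATF4 targets, 0.02 and 0.03 for purine synthesis and 0.05 and 0.01 for DNA replication, where the test pointed down. For hypoxia (-0.12 and 0.02), mesenchymal genes (-0.09 and 0.35) and fibroblast markers (-0.26 and 0.35) the test also pointed down. For p53 targets (-0.08 and 0.02), other receptor tyrosine kinases (-0.05 and 0.27) and basal markers (-0.60 and 0.97) it pointed up. Without scaling, the median of all genes was 0.126, against 0.014 with TMM, and several list medians near 0 changed sign. They went to 0.05 for the TCA cycle, 0.06 for pyrimidine genes, 0.03 for p53 targets, 0.06 for other receptor tyrosine kinases, 0.03 for mesenchymal genes and 0.01 for interferon-stimulated genes. With DESeq2 size factors the median of the ATF4 targets was -0.01.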

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

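The alternatives in this part were planned, and no test in it was chosen after the results were seen. The numbers of changed genes, 7466 in all and 1448 by at least 2-fold, stayed within 1.5 times in the settings that used counts, and leaving out each library in turn gave 6380 to 7625 genes, 1388 to 1531 by at least 2-fold and 11 to 12 lists. On log2(FPKM + 1) values limma called 7336 genes but only 334 by at least 2-fold; test, scale and scaling all differ there. Of these, 321 were among the 1448. The 12 gene lists became 20 by fry, which tests whether a list's genes move on balance in a direction rather than against other genes. The lists added were both glutamine enzyme lists, the TCA cycle, p53 targets, the EGFR family, and luminal, basal and endothelial markers (fry adjusted p = 0.00131 to 0.0497). By camera with an estimated correlation the 12 lists became 0 (6 at an unadjusted p under 0.05). The ERK output list also fell out on log2(FPKM + 1) values and without Control replicate 1, Control replicate 2 or DON replicate 2 (adjusted p = 0.212, 0.101, 0.0783 and 0.0569, in a range of 0.0038 to 0.212). The other 11 lists kept their direction in the settings with a preset correlation, with an adjusted p of at most 0.0306. With the replicate block the counts were 7053 genes, 1452 by at least 2-fold and 12 lists. No shared effect by replicate number was seen. Same-numbered libraries had deviations from their group means that correlated at r = -0.135 to -0.023 across genes, and differently numbered ones at -0.062 to 0.13. Of the 6 libraries 0 correlated best with its own number. With 3 libraries per group this cannot tell whether same-numbered libraries were handled together.

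For the 150 genes selected by the rule for named genes, 1787 of 1800 checks kept the direction and the side of the threshold, 12 passed only in the alternative, 1 lost its call (on log2(FPKM + 1) values) and 0 changed sign with a call. Of the 144 that changed, 143 kept their call in every alternative run and the exception was PDGFRA. The checks that came to pass were those of EGFR, B2M and EGFL7. Depth limits what can be said of genes under about 1 CPM.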

Other observations

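The tests of symbol families, of changed symbols, of scaling, of background as a part of the excess and of other splits (apart from the splits for families) were chosen only after the results they bear on were seen. Families of genes that share the leading letters of their symbol, with at least 8 tested members, were tested with camera in the same way as the lists. Of 224 families 10 passed, 6 higher and 4 lower in DON, against 135 by fry and 0 by camera with an estimated correlation (7 at an unadjusted p under 0.05), where each had an adjusted p of 0.938. Without the low-count filter and on log2(FPKM + 1) values 19 passed, and leaving out each library in turn gave 10 to 12. Matrix metalloproteinases rose in 8 of 15 cases and fell in 2 (camera adjusted p = 0.00366): beside MMP3 and MMP1, MMP10 rose from 0.465 ± 0.168 to 3.96 ± 0.328 CPM and MMP9 from 0.756 ± 0.268 to 4.59 ± 0.336 CPM (mean ± SD, n = 3). Dual-specificity phosphatases, many of which inactivate MAP kinases, rose in 13 of 19 cases and fell in 3 (camera adjusted p = 3.08e-05), with DUSP1 going from 69.5 ± 8.11 to 355.3 ± 21.6 CPM and DUSP8 from 9.68 ± 1.44 to 38.7 ± 3.09 CPM. Subunits of the TIMM complexes, which import proteins into mitochondria, rose in 12 of 14 cases and fell in 0 (camera adjusted p = 0.00366), among them TIMM8A (log2 fold change 1.02), TIMM8B (0.83) and TIMM17A (0.69).

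RNA polymerase subunits rose in 17 of 31 cases and fell in 4 (camera adjusted p = 0.0155), and the 4 with the smallest p all belong to RNA polymerase III, which makes tRNA and 5S rRNA: POLR3A rose from 116.6 ± 3.44 to 253.3 ± 3.18 CPM, and POLR3E, POLR3G and POLR3C had log2 fold changes of 1.09, 1.36 and 0.98. The RRP and UTP families of ribosomal RNA processing rose in 8 of 8 and 9 of 10 cases (camera adjusted p = 3.11e-05 and 0.032), in part the same genes as the ribosome biogenesis list. Aldehyde dehydrogenases fell in 10 of 16 cases and rose in 0 (camera adjusted p = 0.00849), with ALDH1A3 going from 491.9 ± 25.3 to 237.1 ± 18.1 CPM and ALDH3A2 from 59.1 ± 2.62 to 23.1 ± 2.86 CPM. Alpha-mannosidases fell in 7 of 8 cases (camera adjusted p = 0.0324), among them MAN1B1 (-0.94) and MAN2B2 (-0.91). The RPL and RPS families, which include pseudogenes and other genes such as RPS19BP1 (0.83), were the others that fell. All 33 genes taken from these families by smallest p and not named before kept their call in each of 396 checks under the other settings.

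Ribosomal protein mRNAs on the list fell by 0.42 on the log2 scale at the median while genes that assemble ribosomes rose. EEF1A1, a translation elongation factor gene chosen after its value was seen, fell from 12070 ± 295 to 4095 ± 207.8 CPM. Loss of short transcripts is argued against as the whole cause, within the limits of the match given below. Lists of other genes matched on length and level, 10000 in all, had a middle median of -0.16 with a central 95% range of -0.33 to 0.01. The match was not exact: the other genes were less abundant (median log2 CPM 8.97 against 9.65). They were also somewhat longer (median log2 length relative to all genes -0.43 against -0.54). The highest of 4 equal groups by mean CPM had a median log2 fold change of -0.044, against 0.04 in the group below. A closer match on level could therefore lie lower. The matched genes were drawn independently of each other, so the range leaves out shared movement of ribosomal protein genes and may be too narrow. Across other genes, longer ones had if anything lower fold changes (Spearman's rho -0.117, genes not being independent). Reads moved to pseudogenes are argued against. The summed level of 243 genes with symbols like those of ribosomal protein pseudogenes went from 1053.3 ± 41.8 to 810.49 ± 9.87 CPM. This is a gain of -1.81% of the loss in the 45 ribosomal protein genes on the list (from 56069 ± 2300 to 42642 ± 751 CPM). Ribosomal protein genes outside the list are not in that sum, while the 243 were not limited to copies of listed genes. RPLP0P2 among the 243 rose. So did RPS19BP1 (from 62.9 ± 7.40 to 111.8 ± 4.83 CPM), a protein-coding gene that the choice by symbol took in. Scaling moves all genes alike, so it is argued against for the list's place below other genes: its median lay -0.44 from that of all tested genes. The list's own median was -0.42 with TMM and -0.31 with no scaling, so the size of the fall depends on scaling. A candidate explanation, as a hypothesis found and tested on the same data, is that DON lowers these mRNAs in T24 cells; whether this follows growth signalling, culture density or slower division was not tested.

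More genes rose than fell by at least 2-fold, and DON libraries had more genes with a count. Depth is argued against: thinned to 29616156 counts, the lowest DON library still had 272 more genes with a count than the highest Control library. Background reads from DNA or unspliced RNA would raise nearly all genes of low level. For the tested genes this is argued against: 60.1% of the changed genes in the lowest of 4 equal groups by mean CPM rose (762 against 506 that fell). Genes removed by the low-count filter, where background would show most, are not covered. Without that filter 1066 genes rose and 538 fell by at least 2-fold, against 936 and 512 with it. Background as a part of the excess stays open, since in that group 530 genes rose and 249 fell by at least 2-fold (68% higher), against 100 and 92 in the highest group (52.1%), and the values do not separate background from genes induced from a low level. Scaling stays open. The share of rises among genes changed at least 2-fold was 62.8% to 76.0% under the 3 scalings run, but a downward shift of all genes by 0.13 on the log2 scale would make rises and falls equal. The 3 scalings differed by up to 0.127 in the median of all genes, none of them lay more than 0.015 below TMM, and no value here fixes total RNA per cell.

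Many protein-coding genes were listed at 0 in every library. Of 496 protein-coding genes whose symbol in the table differs from the GENCODE 29 symbol of the same NCBI Gene ID, 493 (99.4%, exact 95% interval 98.2% to 99.9%) were at 0, against 2475 of 18766 (13.2%) with an unchanged symbol. For the genes with a changed symbol, the difference of 86.2 percentage points argues against silence in T24 cells as the cause, since a change of name has no link to expression. It does not bear on the 2475 genes at 0 with an unchanged symbol. A candidate explanation is that counts made under older symbols were lost when they were joined to current names. This would remove most aminoacyl-tRNA synthetases from view. Among tested lists, purine synthesis and the mesenchymal and TGF-beta response genes each had 2 members at 0 with a changed symbol. The symbol families come from the same values and could lack members in the same way. The 13 mitochondrial mRNAs were also at 0, which this test does not cover.

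With 3 libraries per group there are 10 splits of the 6 libraries, too few for a share under 0.05. In each case 1 of the 10 splits, the real one, gave a result as large. It gave 7466 changed genes against a highest value of 0 among the other splits (edgeR, 228 genes at an unadjusted p under 0.05), and 1448 against 0 by at least 2-fold. In a mixed split the difference between DON and Control falls largely within the groups and widens their spread. The 0 genes there therefore cannot speak for or against chance. The real split gave 12 lists against a highest value of 10 and 10 families against a highest value of 6. The mixed splits called 3 to 10 lists and 1 to 6 families by camera with a preset correlation. Part of the difference between DON and Control remains in each mixed split, so these numbers are not a rate of false calls.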
